A study of Mus musculus with 28 samples.

How the data were processed

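Motor cortex was taken from 14 mice that carried Cx3CR1-Cre with a floxed TRAP allele, a pair of transgenes that tags ribosomes in cells expressing Cx3cr1, which in brain tissue are mainly microglia. In TRAP (translating ribosome affinity purification) the tagged ribosomes are precipitated from the lysate together with the mRNA bound to them. Each mouse gave 1 TRAP library and 1 total lysate library, so that the series holds 28 libraries. Of the 14 mice, 7 stayed in their home cage and 7 ran on a rotarod for 1 h before tissue was collected. Each condition held 4 females and 3 males per the labels, and each condition had 4 mice in cohort 1 and 3 in cohort 2. Condition, fraction, sex and cohort were taken from the sample titles.

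The deposited values were raw counts per gene symbol, whole numbers with no normalisation, in 1 table of 24391 symbols. The authors started from poly(A) RNA isolated with an RNeasy kit and made libraries with Nextera XT, per the labels' protocols. STAR 2.7.7a, featureCounts, DESeq2 and the build GRCm38 are named in the submitters' processing notes. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without strand, reads of a gene and of a partner on the opposite strand cannot be told apart. Mitochondrially encoded genes were not analysed here, and the total counts and CPM do not include them. Columns that carry no cohort mark were taken as cohort 1, since their condition, sex, number and fraction match those titles and the columns of cohort 2 carry a mark. No column belonged to samples outside the series (0 such columns).

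Total counts ran from 70090518 to 241381845 per library. Total lysate libraries of cohort 1 held 70090518 to 121179170 and those of cohort 2 155554001 to 179477632. Libraries of a group were compared pairwise for duplicates over genes, and the lowest chi-square per degree of freedom was 69.8, so no pair agreed within sampling noise.

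The main tests were edgeR (4.0.16) quasi-likelihood F tests on the deposited counts, with TMM scaling, the filter filterByExpr, and Benjamini-Hochberg adjustment at 5%. Run and home cage were compared within each fraction, over 14 libraries with cohort as a covariate. TRAP was compared with total lysate over all 28 libraries, as was the difference of the run effect between the fractions. Whether the run effect differed between sexes or cohorts was tested within each fraction. The p-values of the TRAP comparison were also adjusted again over TRAP-enriched genes alone, those with an adjusted p under 0.05 and a log2 fold over 1 against total lysate. Gene lists were tested with limma (3.58.1) camera on log2 CPM at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Of the 38 lists, 15 of cell types and 23 of processes, 36 had the minimum of 5 tested genes. Lists, tests, samples, covariates and the rule for naming genes were fixed before the data were examined. The values called CPM are read counts scaled by library size, computed here with TMM factors within a fraction, or over all 28 libraries where the fractions are set side by side. Y-linked levels and purity used library totals without TMM.

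The rule named the 10 called genes with the largest rise and the 10 with the largest fall, at a mean log2 CPM of at least 1, for the run comparisons, the fractions and their difference, all of them where fewer were called, and the 3 with the smallest p where a direction had none. It added up to 3 called members of each list, and Cx3cr1, P2ry12, Tmem119, Rpl10a, Fos, Arc, Egr1, Npas4, Slc17a7, Gfap and Mbp in every comparison. Predicted or unnamed models were counted and not named. Other genes given as examples of a list were chosen after their values were seen. Gene positions and overlaps come from the GENCODE annotation of GRCm38.

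TRAP and total lysate libraries are paired by mouse in the titles. Deviations of the 2 libraries of a mouse from their group means correlated between -0.54 and 0.38, over 0.1 in 6 of 14 mice, and 5 of 14 mice correlated best with their own partner. The comparison of the fractions carried no block, and the block on the mouse was an alternative.

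The run comparisons in each fraction, the comparison of the fractions, the difference of the run effect between them and the difference between sexes in lysate were tested on simulated data with 200 changed genes each. With 50 genes per fold size, the TRAP comparison recovered 36% of genes changed 1.5-fold, 76% at 2-fold and 96% at 3-fold. The total lysate comparison recovered 50%, 88% and 100%. For the difference of the run effect between fractions the shares were 10%, 40% and 76%, so that most differences of 2-fold or less between the fractions were out of reach. All these shares may be too high for the data. Simulated genes were drawn independently, and 200 changed genes loosen the adjusted threshold, while the real run comparisons called 6 and 5 genes. In those, Fkbp5 at 2.02-fold in TRAP (edgeR adjusted p = 0.0692) and Atf3 at 3.48-fold in lysate (0.0828) were not called.

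Alternatives fixed beforehand were DESeq2 (1.42.0) and limma-voom with sample quality weights, other scalings and filters, no cohort term, sex as a covariate, each cohort and each sex alone, a purity covariate (mean log2 CPM of the homeostatic microglia list minus that of the pan-neuronal list), blocks, and leaving out each library in turn. Chosen after seeing the data were the correction of each library's trend on GC content (lowess span 0.5), the sexes of 2 mice taken from the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y with a threshold of 5 CPM, both together, the fits without those mice, cohort 1 alone and leaving out each library for the difference between sexes, TRAP enrichment from home cage libraries alone, and the carry-over test. Models were also fitted in an exploratory way before the final ones. Xist, planned for the sex check, was left out of it after seeing the data, since it was at 0 counts in most TRAP libraries labelled female. Its counts in total lysate are given below with the 2 mice. GC content was known for 96.2% of tested genes.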

Results

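The data are read counts of poly(A) RNA from motor cortex, in 4 groups of 7 libraries: home cage and run, each as microglial TRAP and as total lysate. The question posed by the design is which mRNAs on microglial ribosomes, and which in the whole tissue, differ after 1 h on the rotarod. Total counts per library ran from 104405588 to 157669964 in home cage TRAP, 104598915 to 241381845 in run TRAP, 84399875 to 169315558 in home cage lysate and 70090518 to 179477632 in run lysate. Over all libraries the first principal component took 63.4% of the variance and the second 25.9%. Each library's deviation from its fraction's mean correlated with GC content across genes, which are not independent replicates, and the sign differed between the cohorts. In total lysate Spearman's correlation ran from -0.82 to -0.57 in the 8 libraries of cohort 1 and from 0.58 to 0.84 in the 6 of cohort 2, and in TRAP from -0.72 to -0.57 and from 0.53 to 0.78. The summed level of 4 Y-linked genes lay on the side of a 5 CPM threshold that the sex in the label calls for in 24 of 28 libraries. The other 4 were both libraries of 2 run mice of cohort 2, labelled Male1 and Female2. The TRAP library labelled Female2 was at 15.4 CPM, above the female libraries and below the 39.4 to 161 CPM of male libraries with matching labels.

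Microglial mRNAs were far more abundant in TRAP than in the lysate the ribosomes came from. All 24 homeostatic microglia genes were higher in TRAP than in total lysate, by a median log2 fold of 6.45. Of 22 activated microglia genes, 16 were called higher and 1 lower, with a median of 2.54. Cx3cr1, the fractalkine receptor whose promoter drives the Cre, was 6.92 ± 0.14 (SE) higher on the log2 scale, Tmem119 6.55 ± 0.13, the purinergic receptor P2ry12 5.69 ± 0.19 and Csf1r, the receptor for the growth factor microglia need, 6.29 ± 0.11. With all libraries scaled together, mean Cx3cr1 was 1665 ± 430 CPM (SD, n = 14) in TRAP and 13.6 ± 1.98 in lysate. Border-associated macrophage genes were also higher, with 11 of 11 higher and a median of 6.20 (Pf4 6.41 ± 0.15, Stab1 6.24 ± 0.18). Cx3cr1 lies at chromosome 9 119901616 to 120069879 on GRCm38, minus strand. Its log2 fold was 6.62 in cohort 1 and 7.31 in cohort 2. Among the largest rises were Tspan32 (7.68 ± 0.48), Cd209b (7.63 ± 0.48), the chemerin receptor Cmklr1 (7.56 ± 0.24) and the complement gene C1qa (7.27 ± 0.14).

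Markers of neurons and oligodendrocytes were lower in TRAP. All 12 pan-neuronal genes were called lower, with a median of -1.48, as were 10 of 10 inhibitory neuron genes (median -1.19, Gad1 -1.83 ± 0.15) and 11 of 12 oligodendrocyte genes (median -1.40). Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was at 309 ± 123 CPM in TRAP against 722 ± 483 in lysate, Mbp, a myelin protein, at 673 ± 251 against 1892 ± 575, and the astrocyte filament Gfap at 32.3 ± 8.42 against 92.0 ± 20.5 (SD, n = 14, all libraries scaled together). The largest falls included the serotonin receptor gene Htr2a (-4.02 ± 0.36) and the channel gene Trpc1 (-3.46 ± 0.28). With an estimated correlation the adjusted p of these 3 lists was 0.195 each. Endothelial genes went the other way, with 11 of 12 higher and a median of 1.51 (Pecam1 3.02 ± 0.16, Cldn5 2.66 ± 0.21, list adjusted p = 0.0995 with an estimated correlation). Of 10 mural cell genes 5 were called higher and 1 lower (median 0.55), and the list did not pass (adjusted p = 0.588).

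Of the process lists, 77 of 79 cytosolic ribosomal protein genes were higher in TRAP (median 1.81, Rpl10a 1.61 ± 0.11), as were 17 of 22 lysosomal genes (median 2.71) and 12 of 16 genes of purinergic signalling, among them the ATP-degrading Entpd1 at 5.34 ± 0.13. With an estimated correlation the adjusted p was 0.195 for ribosomal proteins, 0.0929 for the lysosome and 0.0139 for purinergic signalling. Of the nuclear-encoded oxidative phosphorylation genes 32 of 49 were lower (median -0.35), and of the cholesterol synthesis genes 17 of 19 (median -0.66), with an adjusted p of 0.523 and 0.0929 at an estimated correlation. Among single genes, edgeR's quasi-likelihood test called 5697 higher and 6773 lower of 16880 at an adjusted p under 0.05. At the preset correlation 24 of 36 lists passed, 13 higher and 11 lower. With an estimated correlation 4 passed: homeostatic microglia (adjusted p = 0.0166), activated microglia (0.0380), border-associated macrophages (0.0139) and purinergic signalling (0.0139). In cohorts 1 and 2 alone 10568 and 11861 genes were called, 10031 and 10705 of them shared with the full comparison.

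**Figure D1:**
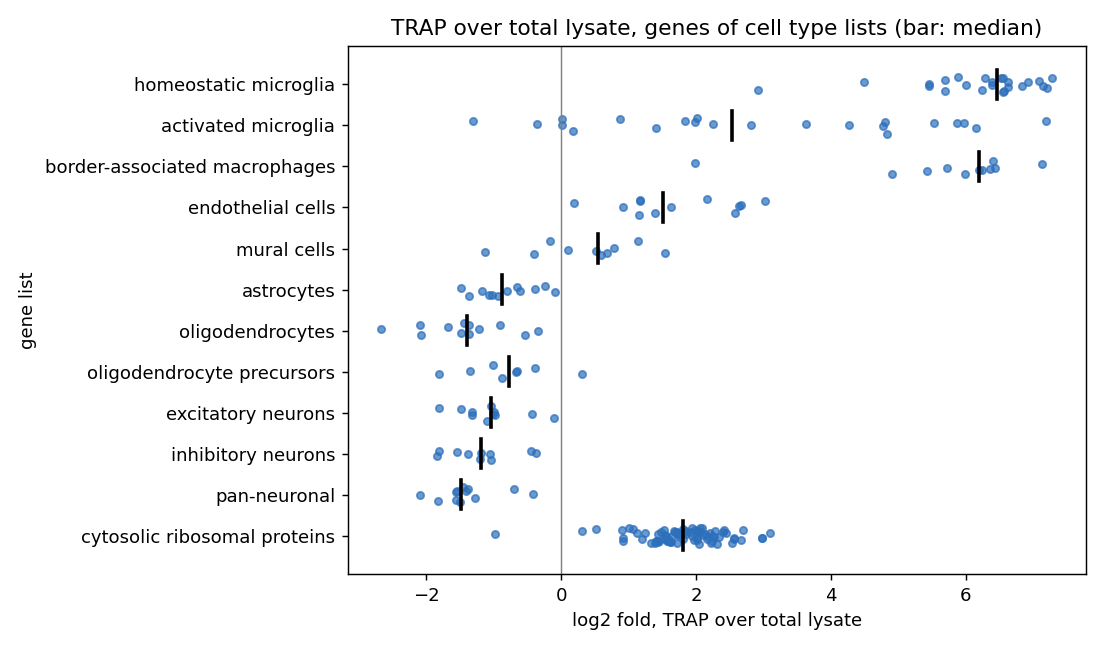
Log2 fold of TRAP over total lysate (x axis) for each gene of 12 lists (y axis), with 1 point per gene and a bar at the list's median. Homeostatic microglia and border-associated macrophage genes have medians of 6.45 and 6.20, and activated microglia genes 2.54. Endothelial and ribosomal protein genes have medians of 1.51 and 1.81, and neuronal and oligodendrocyte genes lie below 0.

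After 1 h on the rotarod, edgeR called 6 genes in TRAP, all higher in the run mice, of which 5 are named. Tsc22d3, a glucocorticoid-induced leucine zipper protein, rose from 217 ± 58.3 to 598 ± 212 CPM (SD, n = 7), a 2.67-fold difference (log2 1.42 ± 0.18 SE, edgeR adjusted p = 0.00324). Tsc22d3 was not among the TRAP-enriched genes. With all libraries scaled together its mean was 485 CPM in TRAP and 291 in lysate, so its rise is not shown to come from microglia. Ddit4, an inhibitor of mTORC1 induced by stress and glucocorticoids, rose 3.54-fold (log2 1.83 ± 0.32, adjusted p = 0.0497), and Rgs1, a regulator of G protein signalling in immune cells, 3.05-fold (1.61 ± 0.24, 0.0129). Apold1, an early response gene of vascular cells, rose 2.51-fold from 7.10 ± 1.90 to 17.5 ± 1.93 CPM (1.33 ± 0.16, 0.00324), and Tagap, a GTPase-activating protein of immune cells, 2.00-fold (1.00 ± 0.16, 0.0179). For each of the 5, all 7 run libraries lay above every home cage library of their own cohort. The genes were chosen by p in these same libraries, so neither this nor the folds within cohorts is independent support. Both cohorts gave the same direction: Tsc22d3 1.68 ± 0.25 and 1.04 ± 0.20, Ddit4 1.97 ± 0.52 and 1.59 ± 0.23, Rgs1 1.75 ± 0.28 and 1.41 ± 0.41, Apold1 1.59 ± 0.20 and 0.96 ± 0.25, Tagap 1.12 ± 0.16 and 0.82 ± 0.28.

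These genes lie, on GRCm38, at chromosome X 140539528 to 140600659 (Tsc22d3, minus strand), chromosome 10 59949669 to 59951834 (Ddit4, minus), chromosome 1 144242296 to 144249242 (Rgs1, minus), chromosome 6 134981718 to 134986836 (Apold1, plus) and chromosome 17 7926000 to 7934897 (Tagap, plus). Tagap shares 716 exon bases with an antisense gene on the opposite strand and has a paralog, Tagap1, at 0.32 ± 0.13 (adjusted p = 0.999), so its counts are uncertain. No exon overlap was annotated for the other 4. No gene was called lower by edgeR or limma-voom (14 calls, all higher), while DESeq2 called 35 higher and 7 lower. The 3 genes with the smallest p in that direction, Tnfaip2 (-0.79 ± 0.18), Gpr84 (-0.89 ± 0.21) and Degs2 (-0.90 ± 0.21), each had an adjusted p of 0.233. Microglial identity genes did not pass: Cx3cr1 -0.09 ± 0.13, Tmem119 0.07 ± 0.14 and P2ry12 0.02 ± 0.23. Of 15644 genes tested, 557 had an unadjusted p under 0.05, where 782 would be expected by chance. No gene was called in cohort 1, cohort 2, females or males alone or without the cohort term. Leaving out the home cage library Female1 of cohort 1 or the run library Male1 of cohort 1 left 3 calls, and leaving out the run library Female1 of cohort 2 gave 10.

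**Figure D2:**
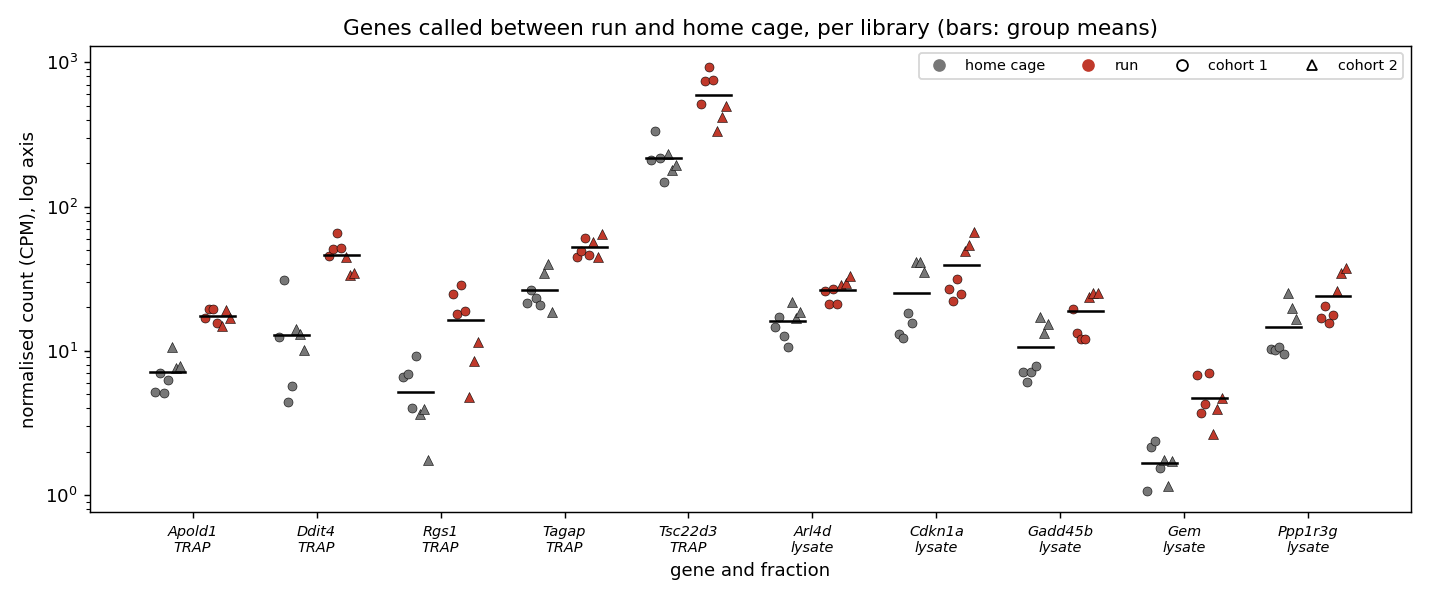
Normalised read counts (CPM, log axis) of the genes called between run and home cage, in the fraction in which each was called, with 1 point per library and bars at group means (n = 7). Grey is home cage and red is run, circles are cohort 1 and triangles cohort 2. Mean Tsc22d3 in TRAP is 217 in home cage and 598 in run mice.

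Glucocorticoid-responsive genes rose as a list in TRAP: 17 of 18 members had a positive fold, with a median of 0.63 on the log2 scale. Tsc22d3 and Ddit4 were called over all genes, and 7 members passed when adjusted over the list alone, among them the chaperone Fkbp5 (1.02 ± 0.19), the clock gene Per1 (0.82 ± 0.19) and Sult1a1 (0.59 ± 0.14). Immediate early genes, transcribed within minutes of stimulation, rose as a list too, with 19 of 21 positive, a median of 0.47, 0 called over all genes and 7 adjusted over the list alone. Those included Klf4 (1.01 ± 0.19), Fosb (1.18 ± 0.33), Fos (0.82 ± 0.23) and Arc (0.74 ± 0.24), while Egr1 was at 0.25 ± 0.17 and Npas4 at 0.70 ± 0.71. Of the 21 immediate early genes, 11 were called lower and 8 higher in TRAP than in total lysate. With all libraries scaled together, mean Arc was 78.4 CPM in TRAP and 272 in lysate, and Fos 15.45 and 40.2. Fosb was at 2.87 and 3.32 CPM, and Klf4 at 14.6 and 1.29. A rise in TRAP of a gene that is lower there than in lysate is not shown to come from microglia. The adjusted p was 9.54e-16 for the glucocorticoid list and 1.50e-12 for the immediate early genes, and 0.0266 for each with an estimated correlation. Medians in cohorts 1 and 2 were 0.54 and 0.60 for the glucocorticoid list and 0.56 and 0.27 for the immediate early genes.

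The other 6 called lists passed in TRAP at the preset correlation and not with an estimated one. All 79 ribosomal protein genes had a positive fold, with a median of 0.19 (adjusted p = 7.02e-11, and p = 0.869 with an estimated correlation), from a median of 0.02 in cohort 1 and 0.43 in cohort 2. Oxidative phosphorylation (median 0.09, adjusted p = 0.00734, and p = 0.869 with an estimated correlation) was likewise at -0.01 in cohort 1 and 0.21 in cohort 2. Without the 2 mice whose sex markers go against their labels the ribosomal protein median was 0.02 (adjusted p = 0.317) and that of oxidative phosphorylation -0.04 (0.476). Late activity-regulated genes had a median of 0.13 (adjusted p = 0.0101, and p = 0.507 with an estimated correlation), with Gadd45b at 0.95 ± 0.22 and Sik1 at 1.00 ± 0.24. Of the neuronal lists, 2 were higher in run mice, inhibitory neurons by a median of 0.17 (adjusted p = 0.0235) and pan-neuronal genes by 0.17 (0.0401), and endothelial genes were lower, with a median of -0.15 (0.0356). With an estimated correlation the adjusted p of these 3 was 0.507, 0.869 and 0.869. Excitatory neurons (median 0.07, adjusted p = 0.207) and striatal neurons (median 0.16, 0.179) did not pass at the preset correlation. Without the 2 mice the medians of inhibitory neurons, pan-neuronal and endothelial genes were 0.16 (adjusted p = 0.0534), 0.08 (0.112) and -0.18 (0.197), and that of late activity-regulated genes 0.22 (0.00214). In cohorts 1 and 2 the medians were 0.25 and 0.04 for late activity-regulated genes, 0.19 and 0.18 for inhibitory neurons, 0.07 and 0.22 for pan-neuronal genes and -0.17 and -0.36 for endothelial genes. The purity measure (mean log2 CPM of homeostatic microglia genes minus that of pan-neuronal genes) was 3.35 ± 0.64 in home cage and 3.15 ± 0.63 in run TRAP libraries (SD, n = 7), and 3 lists passed with it as a covariate. Of 100 splits of the mice, the real one included, 25 gave as many called lists as the 8 found.

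Over the 3487 tested genes enriched in TRAP, edgeR called 13, all higher in run mice, while DESeq2 called 21 higher and 8 lower, limma-voom 19 and 2, and edgeR after GC correction 16 and 4. Besides Apold1, Rgs1, Tagap, Ddit4 and 1 unnamed model, these were 8 genes, named after their values were seen: the NF-kB inhibitor Nfkbia (1.05 ± 0.19, adjusted p = 0.0132), the transcription factors Cebpb (1.05 ± 0.20, 0.0170) and Klf4 (1.01 ± 0.19, 0.0170), Fkbp5 (1.02 ± 0.19, 0.0170), Nuak2 (0.91 ± 0.17, 0.0170), Rab7b (0.92 ± 0.18, 0.0201), Abhd15 (0.69 ± 0.14, 0.0239) and Jade2 (0.60 ± 0.11, 0.0170). Exons of Cebpb and Abhd15 share 312 and up to 883 bases with protein-coding genes on the opposite strand. Enrichment was taken over all libraries, run mice included. In the home cage libraries alone Apold1 was not enriched (log2 fold 0.64 over lysate), and with enrichment from these the count was 12, all higher and all among the 13. Endothelial genes had a median of 1.51 over lysate, so the rise of Apold1 is not shown to come from microglia. The count was 6 in cohort 1 alone, 0 in cohort 2 alone and 7 without the 2 mice whose sex markers go against their labels. It was 7 without the home cage library Male2 or the run library Male1, both of cohort 1.

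In total lysate edgeR called 5 genes, all higher in run mice, while DESeq2 called 28 higher and 12 lower and limma-voom 43 and 6. Gem, a GTPase induced by depolarisation, rose 2.79-fold from 1.68 ± 0.48 to 4.74 ± 1.62 CPM (SD, n = 7; log2 1.48 ± 0.24 SE, edgeR adjusted p = 0.0264). Gadd45b, an activity- and stress-induced gene, rose 1.84-fold (0.88 ± 0.13, 0.0264), and Cdkn1a, a cell cycle inhibitor induced by stress and glucocorticoids, 1.63-fold (0.71 ± 0.12, 0.0369). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, rose 1.68-fold (0.75 ± 0.12, 0.0264) and Arl4d, a small GTPase, 1.67-fold (0.74 ± 0.12, 0.0264). For all 5, the 7 run libraries lay above every home cage library of their own cohort. As in TRAP, the choice of the genes by p in the same libraries favours this and equal directions in the cohorts. In cohorts 1 and 2 the log2 folds were 1.62 ± 0.34 and 1.28 ± 0.29 for Gem, 1.02 ± 0.21 and 0.68 ± 0.14 for Gadd45b, 0.84 ± 0.18 and 0.52 ± 0.14 for Cdkn1a, 0.80 ± 0.16 and 0.66 ± 0.19 for Ppp1r3g and 0.78 ± 0.18 and 0.66 ± 0.14 for Arl4d.

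The 5 genes lie on GRCm38 at chromosome 4 11704457 to 11714752 (Gem), chromosome 10 80930073 to 80932204 (Gadd45b), chromosome 17 29090976 to 29100727 (Cdkn1a), chromosome 13 35958839 to 35970388 (Ppp1r3g) and chromosome 11 101665541 to 101667832 (Arl4d), all on the plus strand. Exons of Cdkn1a share 273 bases with an uncharacterised model on the opposite strand. The 3 genes with the smallest p among those lower, none of which passed, were the microglial receptor P2ry13 (-0.72 ± 0.15, adjusted p = 0.157), Opn3 (-0.57 ± 0.13, 0.281) and Ttc30b (-0.59 ± 0.14, 0.312). Among activity markers Arc was at 0.66 ± 0.22, Npas4 at 0.53 ± 0.18, Fos at 0.47 ± 0.18 and Egr1 at 0.02 ± 0.10, none past the threshold over all genes. Of 16522 genes, 1206 had an unadjusted p under 0.05, where 826 would be expected by chance. The count was 0 in each cohort and each sex alone, without the cohort term and without the 2 mice whose sex markers go against their labels. It was 0 without the home cage library Female1, Male1 or Male2 of cohort 1 or Female1 of cohort 2, or the run library Male1 or Male2 of cohort 1 or Female1 or Female2 of cohort 2, 1 without the run library Female1 of cohort 1, and 8 without the home cage library Male1 of cohort 2.

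At the preset correlation 7 lists passed in total lysate, and with an estimated one none (0 of 36). All 18 glucocorticoid-responsive genes had a positive fold (median 0.43, adjusted p = 2.11e-13, and p = 0.0702 with an estimated correlation), with 11 passing when adjusted over the list alone, among them the kinase Sgk1 (0.79 ± 0.18), Tsc22d3 (0.59 ± 0.14) and Errfi1 (0.42 ± 0.10). Of 21 immediate early genes 19 were positive (median 0.47, adjusted p = 1.14e-12, and p = 0.0743 with an estimated correlation) and 11 passed over the list alone, with Atf3 at 1.80 ± 0.33, Dusp5 at 1.01 ± 0.22, Fosb at 0.97 ± 0.18 and Egr4 at 0.53 ± 0.13. The late activity-regulated genes (median 0.14, adjusted p = 0.000237) and the genes of the unfolded protein and integrated stress response (median 0.17, 5.03e-06; Manf 0.34 ± 0.09) also passed, as did ribosomal proteins (median 0.14, 1.14e-12) and oxidative phosphorylation (median 0.10, 0.000218). With an estimated correlation the adjusted p was 0.0743 for the late activity and stress response lists, 0.431 for ribosomal proteins and 0.520 for oxidative phosphorylation. Endothelial genes were lower (median -0.37, adjusted p = 0.000790, and p = 0.196 with an estimated correlation), with Slco1a4 at -0.64 ± 0.20 and Itm2a at -0.49 ± 0.13. In cohorts 1 and 2 the medians were 0.54 and 0.37 for the glucocorticoid list, 0.40 and 0.39 for immediate early, 0.19 and 0.05 for late activity-regulated and 0.17 and 0.17 for stress response genes. They were 0.11 and 0.18 for ribosomal proteins, 0.12 and 0.03 for oxidative phosphorylation and -0.42 and -0.29 for endothelial genes. Of 100 splits of the mice, 14 gave as many called lists as the 7 found.

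**Figure D3:**
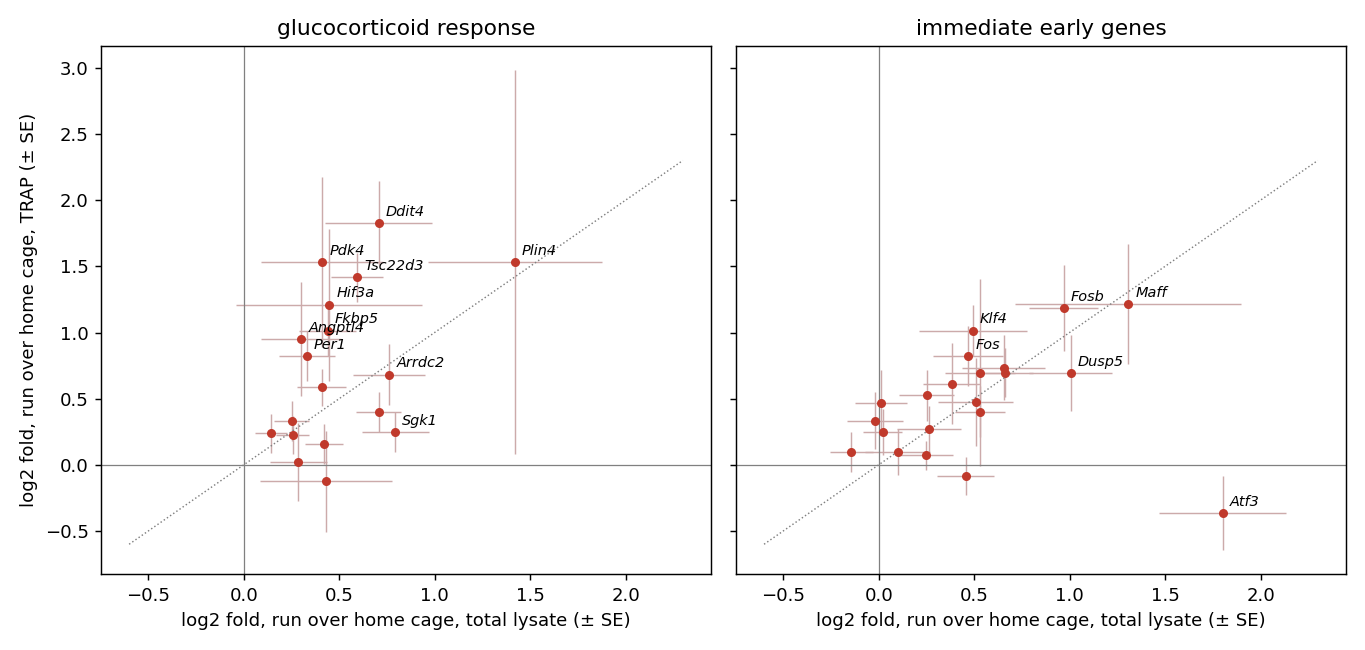
Log2 fold of run over home cage in total lysate (x axis) and in TRAP (y axis) for the genes of the glucocorticoid response and immediate early gene lists, with 1 point per gene, bars of 1 SE and a dotted line of equality. Ddit4 lies at 1.83 in TRAP and 0.71 in lysate, and Atf3 at -0.36 in TRAP and 1.80 in lysate.

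Whether the run effect differed between TRAP and total lysate was tested over all 28 libraries. No gene passed (0 of 16880 with edgeR, 696 with an unadjusted p under 0.05, where 844 would be expected by chance), and 0 of 36 lists passed. Atf3, a stress-induced transcription factor, had the smallest p, with a run effect lower in TRAP than in lysate by -2.15 ± 0.42 on the log2 scale (adjusted p = 0.241), followed in that direction by Pdgfb (-0.68 ± 0.19, 0.863) and Ism2 (0.863), which was at 0 counts in all 7 run TRAP libraries. In the other direction the smallest p belonged to Erbb3 (0.293), at a mean of 0.00284 CPM in home cage and 0.396 in run TRAP, Fbxo47 (0.440), at 0.00187 and 0.173 CPM, and Vaultrc5 (0.440), at 0.00243 and 0.0648 CPM. For these 3 and Ism2 no fold is given, since a group at or near 0 makes it depend on the prior count. For Fos the difference was 0.38 ± 0.30 and for Cx3cr1 0.06 ± 0.21. Genes called in one fraction and not in the other are therefore not shown to differ between the fractions. DESeq2 called 34 genes and limma-voom 1.

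In total lysate the run effect differed between mice labelled female and male for 1086 of 17101 genes, 197 with a higher and 889 with a lower fold of run over home cage in males, and for 0 of 16289 in TRAP (edgeR, 863 with an unadjusted p under 0.05, DESeq2 88, limma-voom 0). The count in lysate was 0 once the trend of each library on GC content was removed, 0 with the sexes of the 2 mismatched mice taken from their markers, 0 without the cohort term and 141 in cohort 1 alone. It ran from 379 to 1791 when 1 library was left out. Called genes with the lower fold in males had a median GC content of 58.3%, those with the higher fold 42.8% and the others 49.4%. Between cohorts no gene differed in the run effect in TRAP (0 of 16289 with edgeR, 804 with an unadjusted p under 0.05, DESeq2 55, limma-voom 0) or in lysate (0 of 17101, 428 with an unadjusted p under 0.05, DESeq2 6, limma-voom 0). Of the gene lists, 14 passed for the difference between sexes in TRAP, 5 in lysate, and 5 and 2 for the difference between cohorts, and 0 of these with an estimated correlation.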

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

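The split counts rest on criteria written before the results were seen, while the tests of exchanged labels, mixed RNA, GC content, sex labels, purity and carry-over were chosen after the results were seen. Criteria of the GC, sex label and carry-over tests were revised once more after their values were known, the sex label test was then split by whether cohort 1 alone called the gene, and the carry-over interval, first taken over list members only, was then taken over mice and members.

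The run effect in total lysate differed between mice labelled female and male for 1086 genes, with a median size of 0.854 on the log2 scale (quartiles 0.699 to 1.04). No other of 100 splits gave as many (1 of 100, highest other 1037), but a split with 1037 calls points to a structure of the samples. With each library's GC trend removed the median fell to 0.317 (quartiles 0.160 to 0.508) with 0 calls, which leaves a GC difference between libraries as a candidate source. The correlation of the fold with GC content across genes went from -0.57 to 0.01, a change that the correction itself brings about. A real effect that follows GC content would be removed in the same way, so the correction cannot decide the source. In cohort 1 lysates, uncorrected, the correlation with GC content of each library's deviation from its cohort mean followed condition and sex. It was -0.35 and -0.57 in home cage females, 0.17 and 0.41 in home cage males, 0.36 and 0.28 in run females and 0.03 and -0.23 in run males. A GC difference between libraries thus cannot be told apart from the tested contrast, in cohort 1 alone too. With the sexes of 2 mice taken from Y-linked genes the median was 0.678 (0.531 to 0.848), and with both changes 0.277 (0.145 to 0.451), each with 0 calls. Cohort 1, whose labels match, called 141 genes alone, 137 of them shared with the full count and in the same direction, which argues against wrong sex labels for those; for the other 949, whose median went from 0.812 to 0.636 (0.517 to 0.797) with the marker sexes while the calls ended, wrong labels stay open, and the sex of the mice stays open for all.

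All 4 libraries of the 2 run mice labelled Male1 and Female2 in cohort 2 lay on the other side of the 5 CPM threshold for Y-linked genes from their label, which an exchange of labels could give, but the TRAP library labelled Female2, at 15.4 CPM, lay below the lowest male TRAP library with a matching label (67.2). In total lysate Xist was at 45 counts in the library labelled Male1 and at 0 in that labelled Female2, which an exchange of labels could also give. Lysates with matching labels held 46 to 272 counts in females, except run Female1 of cohort 1 at 0, and 0 to 1 in males. Mixed RNA is argued against for the libraries labelled Male1, whose highest Y-linked level was 0 CPM against at most 1.12 in female libraries. For the TRAP library labelled Female2 it stays open: its TRAP to lysate ratio of Y-linked CPM was 0.354 against 0.765 to 1.71 in the other male mice, which rests on 1 library. No biological explanation was tested.

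The glucocorticoid and immediate early gene lists rose in TRAP with medians of 0.63 and 0.47. With purity as a covariate the medians were 0.58 and 0.40 and the adjusted p 1.31e-12 and 1.30e-10 (camera at the preset correlation). For purity as measured here, from microglial and pan-neuronal genes alone, this argues against lower purity of the run precipitates as the whole cause. RNA of other cells is not covered by that measure, and the covariate was not run with an estimated correlation. Each list had a smaller camera p in the real split than in any other of 100 (1 of 100 for each, real p 2.65e-17 and 8.32e-14, smallest other 3.19e-13 and 2.50e-11). The 2 lists were those with the smallest p of 36 in the real split, which favours such a share. In 20 and 26 of 100 splits some list reached as small a p (smallest 2.98e-41), so lists as a class do respond to other groupings. Carry-over from neurons may contribute. The expected fold took RNA at the measured pan-neuronal TRAP to lysate ratio to change as the lysate did. Observed minus expected had a median of 0.291 (95% interval 0.0461 to 0.847) for the glucocorticoid list. That whole interval is positive, which argues against neuronal carry-over at that ratio as the whole cause for this list. For the immediate early genes the median was 0.165 (-0.0217 to 0.423), and carry-over cannot be told apart. With no ratio assumed, TRAP minus whole lysate gave 0.107 (-0.232 to 0.590) and 0.0799 (-0.155 to 0.294), so carry-over at a higher ratio stays open for both lists. For endothelial RNA the medians were 0.107 (-0.233 to 0.702) and 0.165 (-0.124 to 0.316), open for both lists. The intervals over members only were 0.119 to 0.867 and 0.0799 to 0.360 for neurons and -0.147 to 0.650 and -0.000598 to 0.234 for endothelial cells. The expected fold was capped at the whole lysate fold, which 14 of 18 and 16 of 21 members reached for endothelial cells. The endothelial values are thus close to the comparison with whole lysate and are no separate test.

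Under 0.05 of the splits gave as many genes called in TRAP (2 of 100 splits gave 6 or more, highest other 101) and among TRAP-enriched genes (3 of 100, 13 real, highest other 152). The same held in total lysate (1 of 100, 5 real, highest other 0), between the fractions (1 of 60, 12470 real, highest other 0) and for the lists between the fractions (2 of 60, 24 real, highest other 24). Each count taken alone thus met the criterion of under 0.05, with no adjustment over the split tests. This makes it unusual among the splits and does not exclude chance. The splits with 101 and 152 calls point to a structure of the samples, which these shares do not exclude. The criterion was not met for the number of lists called between run and home cage, where chance cannot be excluded either. In TRAP 25 of 100 splits gave 8 or more (highest other 17), and in lysate 14 of 100 (7 real, highest other 11). The counts of 0 are met by all 100 splits: for the difference between fractions (highest other 1 gene and 7 lists), between sexes in TRAP (highest other 4) and between cohorts in TRAP and lysate (highest other 130 and 589, again a structure of the samples).

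Of 96 groups of 7 libraries, 6 held a library far from the others, and chance gives about 1 in 20. The ribosomal RNA gene Rn45s took 6.83% of counts in 1 home cage TRAP library of cohort 2 (next 2.32%), which is not alone in that cohort: over both conditions TRAP libraries ran from 0.363% to 6.87% in cohort 2 and from 0.173% to 0.312% in cohort 1. Purity was -4.00 in 1 home cage lysate (next -4.23). In 1 run TRAP library Arc was at 156 CPM (next 84.6), and Mbp at 1149 CPM in 1 (next 625.8). In home cage TRAP, Ddit4 reached 30.8 CPM (next 14.3) and Gfap 37.6 CPM (next 27.8).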

How the results depend on the processing

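Chosen after the data were seen were the GC correction, the sexes from Y-linked genes, leaving out the 2 mice with sex markers against their labels, TRAP enrichment from home cage libraries alone, and cohort 1 alone and single libraries left out for the difference between sexes. Of the values of named genes and lists, 3617 kept their side of the threshold, of which 69 changed sign without a call in either fit, 244 lost the call, 15 gained one and 2 reversed. Where a count moved the cause was not tested, though fewer mice enter the fits within a cohort or sex. Fits in females or males alone went by the labels. They therefore kept run Female2 and run Male1 of cohort 2, whose sex markers go against their labels, under the labelled sex. Genes called in TRAP (6) were 10 with a CPM of at least 1 in 7 libraries, 42 with DESeq2, 14 with limma-voom, and 0 without the cohort term, in cohort 1, cohort 2, females or males alone. TRAP-enriched calls (13) were 29 with DESeq2, 21 with limma-voom, 1 without the cohort term, 6 in cohort 1, 0 in cohort 2, 0 in females, 1 in males, 20 with GC correction and 7 without the 2 mice. Lists in TRAP (8) were 2 with an estimated correlation, 5 without the cohort term, 5 in cohort 1, 2 in females, 19 in males, 3 with the purity covariate and 4 without the 2 mice; reversed were the pan-neuronal list in females (camera p = 0.717) and oxidative phosphorylation without the 2 mice (p = 0.357). Genes in lysate (5) were 40 with DESeq2, 49 with limma-voom, 8 with GC correction and 0 without the cohort term, in each cohort or sex, and without the 2 mice, and lists (7) were 0 with an estimated correlation. Lists between fractions (24) were 4 with an estimated correlation. The difference of the run effect between fractions (0) had 34 genes with DESeq2, 1 with limma-voom and 2 in cohort 2, and 4, 1 and 1 lists in cohort 1, cohort 2 and males. The difference between sexes was 88 in TRAP with DESeq2, and in lysate (1086) 1940 with DESeq2, 141 in cohort 1, and 0 without the cohort term, with GC correction, with sexes from Y-linked genes or both. The difference between cohorts (0) was 55 in TRAP and 6 in lysate with DESeq2.

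Leaving out 1 library gave 3 to 10 genes in TRAP, 7 to 19 TRAP-enriched, 3 to 12 lists in TRAP, 0 to 8 genes and 7 to 9 lists in lysate, and 379 to 1791 genes for the sexes. Lists in TRAP were 3 without home cage Male1, 4 without home cage Male2 or run Male2 and 5 without run Male1, all of cohort 1, and 5 without home cage Male1 or run Female2 of cohort 2. The sex count was 522, 607 and 379 without home cage Female2, Male1 and Male2 of cohort 1, 563 and 1791 without home cage Male1 and Female1 of cohort 2, 390 without run Male2 of cohort 1 and 694 without run Male1 of cohort 2. Home cage and run mice that share a number are not paired: their deviations correlated over 0.1 in 2 of 7 numbers in TRAP and 1 of 7 in lysate, and 1 and 0 of 7 correlated best with their own. A replicate block on the number gave 3 genes in TRAP, 8 TRAP-enriched and 0 in lysate. Between fractions, pairing by mouse moved no count by over 1.5 times. Total counts were at least 70090518 per library, and in simulated data 36% of genes changed 1.5-fold were recovered in TRAP and 50% in lysate.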
